A study of Mus musculus with 4 samples.

How the data were processed

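The data are 4 single-cell RNA libraries from B16F10 tumours, 1 per group: NK cells sorted from the tumour and the tumour suspension, each labelled WT or KO. Libraries were made with the 10x Genomics 5′ v2 kit and sequenced on a NovaSeq instrument, per the labels' protocols. Reads were aligned and counted by the authors with Cell Ranger 6.0.0 against mm10, and Seurat was also used, per the submitters' processing notes; its version is not given in the sources used here. The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode, as whole numbers, after the barcode filter of Cell Ranger. No cell annotation is among the files, and the number and sex of the mice pooled are not given in the sources used here. Each file lists 32285 genes, of which 32235 (99.85%) matched the GENCODE vM21 annotation of GRCm38 (mm10) by identifier, the source of all coordinates.

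Barcodes with at least 500 genes and at most 10% mitochondrial counts were kept. Too few genes removed 147 and 242 barcodes of the sorted and 1712 and 2988 of the tumour libraries (WT before KO), and mitochondrial counts removed 101, 169, 651 and 547 in the same order. Doublets were called by Scrublet in scanpy 1.11.5 and removed: 1864 (11.7%), 843 (8.17%), 1008 (6.42%) and 124 (2.07%). In the sorted library labelled KO the automatic threshold marked 0.04%, so the threshold was set at the share that 0.8% per 1000 cells gives. This left 14059 and 9478 cells in the sorted and 14700 and 5858 in the tumour libraries. The cells of all 4 libraries were clustered together without integration, after scaling to 10000 counts and log1p, on 2000 variable genes, 30 components and 15 neighbours with the Leiden method at resolution 1 and seed 0 (leidenalg 0.10.2, Python 3.11.15). The 30 clusters were named from 18 marker sets. A cluster took a name with at least 3 markers of that set raised 1.5-fold, and every cluster could be named. A class name such as NK cells stands for cells like that type by these markers, and NK cells take in ILC1-like cells.

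Counts of each class were summed per library and given in CPM (per 1000000 counts of the class), with exact 95% Poisson intervals. Ratios have exact conditional binomial intervals and shares of cells have exact binomial ones. Log2 ratios are KO over WT with 1 CPM added to each. A zero count was given a floor of 3 counts over the class. Folds given as at least use this floor, which lies below the upper bound of the exact interval of a zero count. A gene counted as measured at 20 CPM in the higher library, and a gene ranked for naming also needed 30 counts there. In NK cells of the suspension labelled WT, 1 count stood for 13.24 CPM, so list members could be measured there on very few counts. With 1 library per group, no test across samples exists and no p-value is given. For each of 33 gene lists, the median log2 ratio of measured members was set among 10000 random lists of equal size, matched in 20 expression bins, as a description of these libraries. Changes of size were counted at 1.5-fold. To compare shares of cells with a count, cells were thinned to 2000 UMIs (NK and melanoma cells) or 1000 UMIs (other classes), and shallower cells were left out.

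The genes named follow a rule. They were ranked by log2 ratio among measured genes with at least 30 counts in the higher library. For sorted NK cells and melanoma cells these are the 12 highest and the 12 lowest, and for other classes the 5 highest and 5 lowest. Left out were mitochondrial, ribosomal protein, haemoglobin, antigen receptor and predicted genes, Xist and Y-linked genes, and genes whose CPM was under 1/10 of that in another class of at least 50 cells of the same library. Zc3h12a, Ifng, Pou2f2, Pou2af1, Gzmb and Prf1 are always given, and from each list up to 4 members with the largest ratio or highest level. Gene lists, markers, filters, comparisons, this rule and most alternatives were fixed before the data were examined. A few list members outside this rule were named after their values were seen: Fcgr3, Nfkbiz, Serpinb9, Slfn2, Tbx21 and Tfrc in NK cells, Irgm1 in melanoma cells, Spp1 in monocytes or macrophages, and Foxp3, Lag3 and Pdcd1 in T cells. Genes of near-identical families (granzymes, Klra receptors, H2 genes, guanylate-binding proteins, Hspa1a and Hspa1b) can share reads and are uncertain one by one.

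The alternatives were 200 or 1000 genes per cell, 5% or 20% mitochondrial counts, doublets kept, resolution 0.5 or 2, each library clustered alone, TMM factors (edgeR 4.0.16), median-of-ratios factors (DESeq2 1.42.0, R 4.3.3), means of per-cell CPM, thinned cells, 5 CPM as pseudocount, no filter or 100 CPM, all cells of a library, cells without Mki67 and Top2a counts, and means over list members. Chosen after seeing the data were leaving out clusters of low depth (under 1/3 of their library's median UMIs) and splitting cells by Xist and Y-linked counts. With CPM scaling the median log2 ratio of all measured genes was -0.09 in NK cells of the suspension, -0.07 in monocytes or macrophages, -0.10 in T cells and -0.13 in conventional dendritic cells. TMM moved these to 0.22, 0.04, 0.08 and 0.04, so ratios in those classes can be read relative to these medians. In sorted NK and melanoma cells the scaling moved it by less than 0.1.

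The calculation was tested on simulated counts with 200 genes altered by known amounts. For sorted NK cells (5506 genes) and melanoma cells (5682 genes), 95.0% and 95.1% of the intervals of unaltered genes covered the true ratio. All genes made 2-fold higher passed 1.5-fold in these classes and in monocytes or macrophages (5386 genes), 90.0% in T cells (5644 genes) and 82.0% in NK cells of the suspension (5462 genes). Of 20 lists of unaltered genes per class, where chance gives 1, 4 lay outside the central 95% of random lists in melanoma cells, 3 in monocytes or macrophages, 1 each in sorted NK cells and conventional dendritic cells and 0 in T cells and NK cells of the suspension. Barcodes shared between libraries were near the number chance gives, such as 223 against 235.4 for the sorted pair. Calculations also used numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.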

Results

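Single-cell RNA was measured in 4 libraries from mouse melanomas grown under the skin from B16F10, a pigmented tumour line with little surface MHC class I that NK cells can attack. A pair of libraries held natural killer (NK) cells sorted from the tumours, and the other pair held cells of the whole tumour. In each pair, 1 library came from mice with an intact, floxed Regnase-1 gene (labelled WT) and 1 from mice that lack it in NK cells (labelled KO). Regnase-1, encoded by Zc3h12a, is an RNase that degrades transcripts of inflammatory genes. Tumours were taken on day 10 from the WT mice and on day 17 from the KO mice, so genotype and day cannot be told apart. The sorted libraries held 94992254 (WT) and 82470442 (KO) unique transcript counts (UMIs) in 16171 and 10732 barcodes. The tumour libraries held 88202871 (WT) and 71215428 (KO) in 18071 and 9517 barcodes. Median UMIs per barcode were 4951 and 5596 in the sorted libraries and 3146 and 1983 in the tumour libraries, WT before KO. Each group was 1 library, so no difference has a replicate check, and the 95% intervals cover counting error only. Levels are in CPM, the count of a gene per 1000000 counts of a cell class in a library.

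The targeted gene was measured before any other. Zc3h12a (ENSMUSG00000042677, chromosome 4, 125118423 to 125127840, build mm10) was higher, not lower, in NK cells of the libraries labelled KO. In the sorted libraries it stood at 272 CPM (95% interval 268 to 276) in the library labelled KO and 74.9 CPM (73.0 to 76.8) in the library labelled WT, 3.63-fold apart. In NK cells of the tumour libraries it stood at 187 CPM (169 to 206) against 39.7 CPM (8.19 to 116), the latter from 3 counts. In monocytes or macrophages it was alike, at 72.3 CPM (KO) and 69.6 CPM (WT), and in melanoma cells it was near absent, at 4.07 and 3.38 CPM. In T cells of the tumour libraries it stood at 54.7 CPM (KO) and 41.8 CPM (WT), against 224.5 CPM in T cells of the sorted library labelled KO. The libraries carry tags from the 5′ end of transcripts, and the deleted exons are not given in the sources used here, so the level does not check the deletion. Genotypes are therefore given as labelled throughout.

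Counts from the sex chromosomes also differed with the labels. Outside melanoma cells, 4 Y-linked genes (Ddx3y, Eif2s3y, Uty and Kdm5d) summed to 76.4 CPM in the sorted and 57.5 CPM in the tumour library labelled KO, against 7.32 and 7.69 CPM in those labelled WT. Xist, made from the inactive X chromosome of females, stood at 129 and 138 CPM in the libraries labelled KO and 265 and 204 CPM in those labelled WT. Among sorted NK cells with counts of either kind but not both, 48.5% (47.2 to 49.8) had Y-linked counts in the library labelled KO and 4.04% (3.63 to 4.47) in the library labelled WT.

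**Figure D1:**
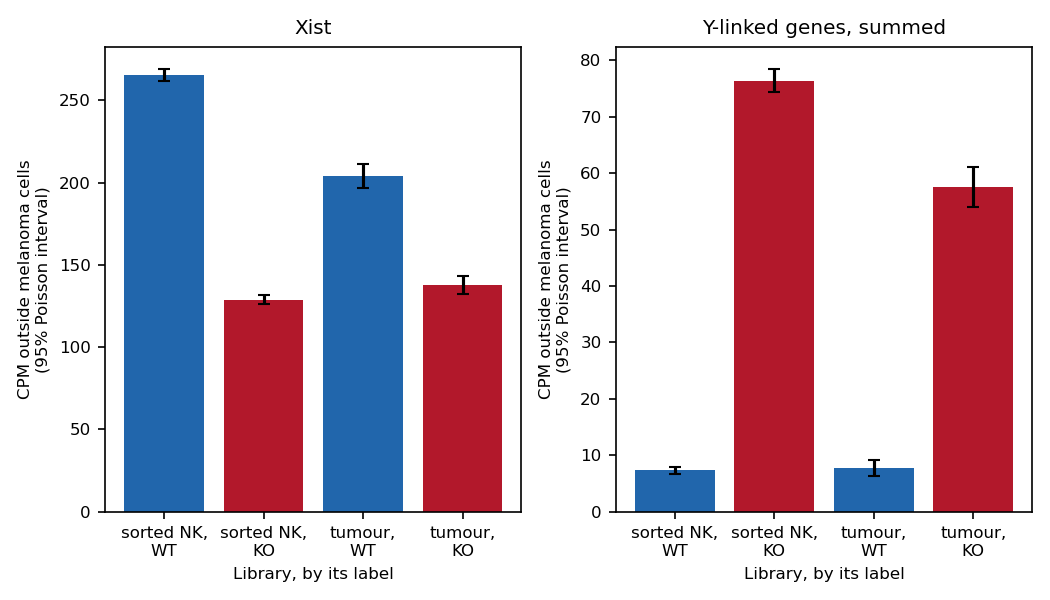
Xist and the sum of 4 Y-linked genes in each library, in CPM of all cells but melanoma cells, with 95% Poisson intervals. The Y-linked sum is 76.4 and 57.5 in the libraries labelled KO and 7.32 and 7.69 in those labelled WT.

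NK cells from the tumour were compared to ask what they express when Regnase-1 is targeted in them. The sorted libraries held 8745 NK cells labelled KO and 14004 labelled WT. The gene of their main cytokine, interferon-gamma, was higher in the library labelled KO, as were 8 of 16 genes of killing granules and death ligands, while 3 of the 16 were lower. Ifng (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892) stood at 204 CPM (201 to 208) against 69.3 CPM (67.5 to 71.2), 2.95-fold higher (2.86 to 3.04). Gzmb, for granzyme B, was 2.82-fold higher (2.80 to 2.84), and Prf1, for perforin, 1.92-fold higher (1.90 to 1.94). Pou2f2 (ENSMUSG00000008496, chromosome 7, 25087344 to 25179726), for the transcription factor OCT2, was 10.0-fold higher (9.30 to 10.8), at 94.8 CPM against 9.45 CPM. Its coactivator gene Pou2af1 stood at 0.457 against 0.305 CPM, a difference not detectable at this depth. In cells reduced to 2000 UMIs each, 20.3% of NK cells labelled KO and 11.01% of those labelled WT had an Ifng count, against 38.8% and 19.4% without that step. For Zc3h12a the shares were 43.5% and 14.6% (77.1% and 30.4% in full), and for Pou2f2 19.6% and 1.79% (45.9% and 4.58% in full). Pmel, a melanocyte gene that NK cells lack, was counted in 0.233% and 0.421% of the same reduced cells (0.698% and 0.850% in full). Median depth of the class was 5875 UMIs (KO) and 4786 UMIs (WT), and 575 and 709 shallower cells were left out of the reduced shares.

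The 12 genes most above their WT level in sorted NK cells labelled KO spanned receptors, granule enzymes and inhibitors of signalling. Irak3, for a kinase-dead inhibitor of Toll-like receptor signalling, stood at 89.8 CPM against 0.178 CPM (chromosome 10, 120141648 to 120202130), 505-fold higher (301 to 925). The granzyme genes Gzmf and Gzmg, whose reads near-identical paralogs can share, were 97.1-fold and 339-fold higher, but among cells with Xist and no Y-linked counts Gzmg had 11 against 8 counts. Cxcr6, for a chemokine receptor of tissue-resident lymphocytes, stood at 100.6 CPM against 2.41 CPM (chromosome 9, 123806475 to 123811760), 41.7-fold higher (36.1 to 48.4). Pdcd1, for the checkpoint receptor PD-1, was 25.4-fold higher (20.4 to 32.0), at 27.1 CPM. Epas1, for the hypoxia factor HIF-2α, was 32.3-fold higher, and the metallothionein gene Mt1 18.3-fold higher. Adgrg1, Aebp1, Ebi3, Tnfrsf13b and Filip1 completed the 12, from 30.2-fold (Filip1) to 326-fold (Adgrg1). The 12 genes furthest below their WT level lay between 3.97-fold (Klf3) and 6.20-fold (Ugt1a7c) lower. Among them, Rab27b, for a GTPase of granule release, stood at 12.4 against 70.1 CPM (chromosome 18, 69979131 to 70141605), 5.63-fold lower. Il18r1, for the receptor of the NK-activating cytokine IL-18, stood at 20.5 against 107 CPM (chromosome 1, 40465552 to 40500854), 5.20-fold lower. Cxcl10, an interferon-induced chemokine gene, was 4.88-fold lower. Plaur, Gpc1, Asap2, Spry2, Olfm1, Pdgfa and Frat2 were also among these 12.

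**Figure D2:**
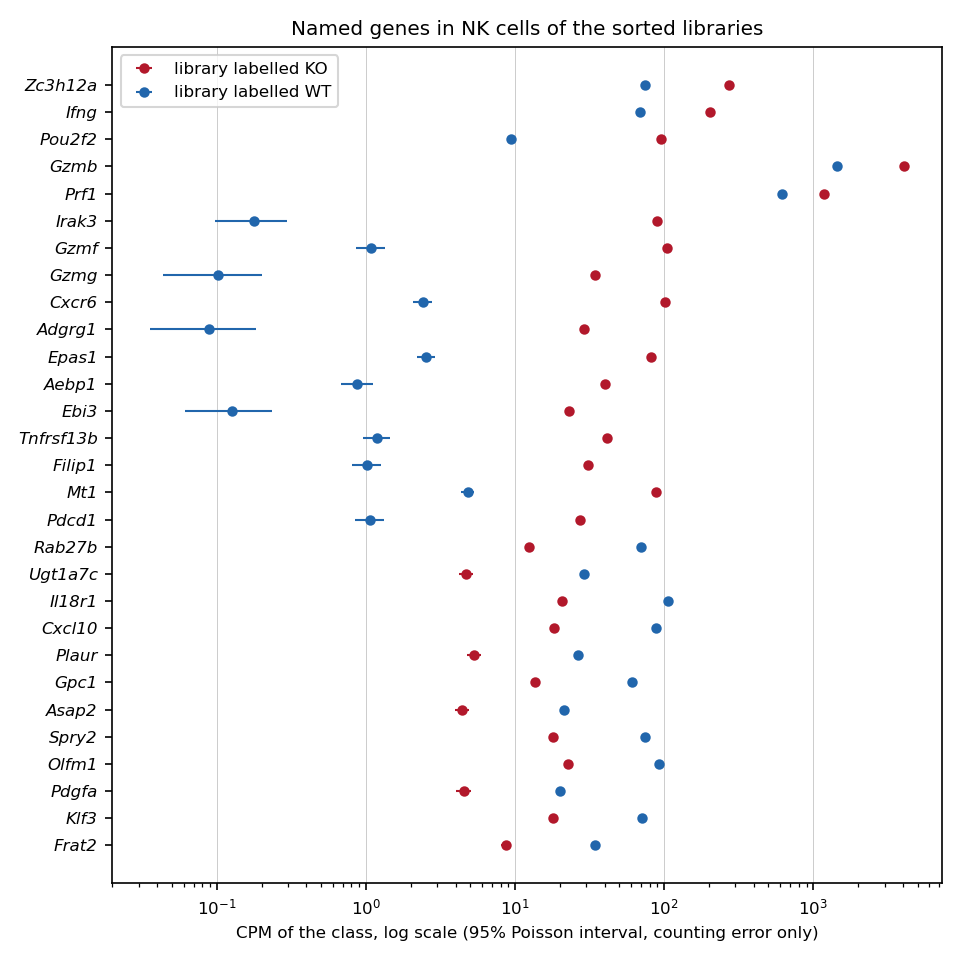
Level of named genes in NK cells of the sorted libraries, in CPM of the class on a log axis, with 95% Poisson intervals that cover counting error only. Zc3h12a lies at 272 in the library labelled KO and 74.9 in the library labelled WT.

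Fixed gene lists set these genes in their groups. Of 11 measured transcripts described as Regnase-1 targets, 9 were at least 1.5-fold higher in the sorted NK cells labelled KO, 1 was lower and 1 lay within 1.5-fold. Their median log2 ratio was 1.496, above all 10000 random lists of like expression. Among them were the genes of the checkpoint CTLA-4 (Ctla4, 3.53) and the costimulator ICOS (Icos, 1.496), with Batf (1.77), Nfkbiz (1.11) and Tfrc (1.09), and only Slfn2 was lower (-1.48). Of 16 granule and death ligand genes, 8 were higher and 3 lower (median 0.64, above all random lists). Gzmf (5.67) and Gzmg (5.01) led, Gzmd (3.51), Gzmc (2.89) and Gzmk (2.05) were also higher, and Serpinb9, for an inhibitor of granzyme B, was lower (-1.19). Proliferation genes were higher in 16 of 22 (median 1.25), led by Pclaf (2.09), Birc5 (2.04) and Ccnb2 (1.99), with no member lower. With cells that held counts of Mki67 or Top2a left out, a filter by members of the list, that median was -0.06. Among 20 hypoxia genes, 9 were higher and 1 lower (median 0.46), with Hilpda at 2.44 and Ddit4 at 1.12. Cholesterol synthesis genes were higher in 6 of 14 and lower in none (median 0.44), and glycolysis genes in 4 of 15, with a median (0.25) inside the central 95% of random lists.

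Other groups of NK genes lay below their WT level. AP-1 and NR4A factors, early genes of receptor signalling and of tissue dissociation, were lower in 12 of 15 (median -0.91), with Atf3 at -1.70, Fos at -1.54 and Nr4a2 at -1.41. The list of dissociation and heat shock genes, which holds Fos and Atf3 too, was lower in 10 of 19 and higher in 4 (median -0.59), with Hspa1a at 2.04. Activating receptors were lower in 11 of 21 and higher in 3 (median -0.80), with Cd28 at -1.53 and Crtam at -1.41, while Fcgr3, for the antibody receptor CD16, was higher (0.96). Inhibitory receptors were split, 6 higher and 6 lower of 17, so that their median (-0.24) and mean (0.36) differed in sign. NF-κB pathway genes were lower in 9 of 18 (median -0.60), with Relb at -1.34 and Tnfaip3 at -1.26, while Bcl2l1, for a survival protein, was higher (1.98). NK transcription factors were lower in 9 of 19 (median -0.58), among them Rora (-1.50), Eomes (-1.05) and Tbx21 (-0.91). Cytokine receptors were lower in 6 of 12 (median -0.63). Genes induced by interferon-gamma were lower in 9 of 19 and higher in none (median -0.52), and those induced by type I interferon were lower in 11 of 14 (median -0.79), with Irf7 at -1.63. Each of these medians but that of the inhibitory receptors lay at or below the 0.01 percentile of random lists. MHC class I genes stayed within 1.5-fold in 18 of 21 (median -0.08). Effector cytokine genes went both ways, 2 higher and 3 lower of 7, with Ccl3 at 0.85 and Xcl1 at -0.89, and their median was -0.497 with CPM scaling and 0.00105 with TMM scaling. TMM moved the median of all measured genes only from -0.078 to 0.016, so the scaling alone does not give this jump. A median over so few members shifts with which of them pass as measured. Residency genes were higher in 4 and lower in 2 of 11 (median 0.31, but -0.62 in NK cells of the tumour libraries), with Itga1 at 2.43. Genes of immature NK cells were lower in 6 of 10 and higher in 2 (median -0.74), Cd27 (-1.31) among the lower. Genes of mature and circulating NK cells were also lower in 6 of 12 and higher in 3, Klrg1 (2.88) among the higher, with a median (-0.34) inside the central 95% of random lists. Ifng, Gzmb and the list medians were taken over unlike clusters. Clusters 2 and 7 held 51.4% and 23.9% of the class labelled KO, and clusters 0, 1 and 6 held 39.3%, 33.3% and 16.3% of the class labelled WT.

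Sex-chromosome counts, which differed with the labels, were used to split the sorted NK cells. Among cells with Xist and no Y-linked counts, Ifng was 3.52-fold, Pou2f2 10.1-fold, Zc3h12a 3.69-fold and Gzmb 3.11-fold higher in the library labelled KO. Among cells with Y-linked and no Xist counts, Ifng was 1.32-fold higher (1.16 to 1.5), Pou2f2 7.30-fold, Zc3h12a 2.89-fold and Gzmb 4.51-fold. Of the 12 genes named as higher, 11 stayed at least 1.5-fold higher among the former cells by the ratio with 1 CPM added. The exception was Gzmg, at 2.85-fold by the plain ratio (1.05 to 8.17), against 1064 and 0 counts among the latter. The median of the Regnase-1 targets was 1.53 in the former cells and 0.76 in the latter. For type I interferon genes these medians were -0.81 and -0.19 (-0.372 to 0.001), and for interferon-gamma induced genes -0.57 and -0.29. Those of residency genes were 0.31 and -0.16 (-0.397 to 0.073), of effector cytokines 0.07 and -1.02, and of maturation and circulation genes 0.28 and -0.498. Measured members were chosen anew in each split, so these medians are partly over different genes. They covered 14 and 10 type I interferon genes, 11 and 10 residency genes, 6 and 8 effector cytokines, and 11 and 13 maturation and circulation genes.

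NK cells of the whole tumour gave another view of the same labels, from 237 cells (KO) and 47 cells (WT). Ifng (491 against 2 counts) was 8.28-fold higher (2.28 to 68.6) and Gzmb 5.48-fold higher (4.49 to 6.76). The log2 ratio of Ifng, 3.003 here, was 0.82 with cells of 200 or more genes and 8.001 in thinned cells. In the latter, 0 of the 12 cells kept of the class labelled WT had an Ifng count. The value 8.001 therefore rests on the 1 CPM added and does not measure a size. Epas1 was at least 5.65-fold higher, Gzmg at least 3.24-fold and Irak3 at least 2.22-fold, each against the floor of 3 counts for the whole class, since the library labelled WT held none. The exact intervals of these ratios began lower, at 4.57, 2.62 and 1.785. For Pou2f2 (96 against 1 count) the ratio was 3.24 (0.568 to 129), so that no difference was detectable. Of the 12 genes most above WT in sorted NK cells, 11 had the same sign here, as had 9 of the 12 most below, and for 8 and 4 of these the interval of the ratio also excluded 1. Across 1434 genes at 100 CPM or more in both pairs, 72.3% had the same sign, with r = 0.69 and rho = 0.61. Genes are not independent replicates, and no p-value is given. The Regnase-1 targets had a median of 1.91, 7 members higher and 2 lower of 12, and AP-1 and NR4A factors one of -1.43. Markers of other cells moved as well, with melanocyte genes lower in 13 of 15 (median -1.64, and -0.56 in thinned cells), MHC class II genes in 6 of 8 (-2.34) and suppressive macrophage genes in 8 of 12 (-0.89). Class depth differed, with medians of 8149 UMIs (KO) and 1233 UMIs (WT), and cluster 7 held 49.4% of the class labelled KO against cluster 1 with 40.4% of the class labelled WT. When simulated at these depths, 39.7% of unchanged genes lay beyond 1.5-fold, and with cells of 200 or more genes the median of the Regnase-1 targets was -0.06.

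The make-up of the tumour suspension was compared to see which cells the tumours held. NK cells were 4.05% of kept cells (3.56 to 4.58, exact binomial) in the library labelled KO and 0.320% (0.235 to 0.425) in the library labelled WT. T cells were 8.06% (7.37 to 8.78) against 2.01% (1.79 to 2.25). Melanoma cells were 43.0% (41.7 to 44.3) against 53.9% (53.1 to 54.7), and monocytes or macrophages 37.1% against 36.3%. Conventional dendritic cells made up 5.05% and 5.48%, plasmacytoid dendritic cells 0.802% and 0.592%, fibroblasts 0.888% and 1.02%, and endothelial cells 0.854% and 0.367%. Of the cells other than melanoma cells, NK cells were 7.10% and 0.694%, T cells 14.1% and 4.36%, and monocytes or macrophages 65.1% and 78.8%. Neutrophils numbered 11 in the library labelled KO and 0 of 14700 cells in the library labelled WT, which allows a share of up to 0.0251% by the exact interval. The filter on genes per cell removed 2988 barcodes (KO) and 1712 (WT), and with 200 genes as the minimum melanoma cells were 50.8% in both and T cells 5.64% and 4.10%. With 1000 genes as the minimum, NK cells were 4.95% (KO) and 0.124% (WT), T cells 8.34% and 0.906%, monocytes or macrophages 36.1% and 23.7%, and melanoma cells 43.3% and 69.7%. The sorted libraries held T cells too, 7.24% (6.72 to 7.78) of the cells labelled KO and 0.228% (0.156 to 0.321) of those labelled WT, beside 92.3% and 99.6% NK cells.

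**Figure D3:**
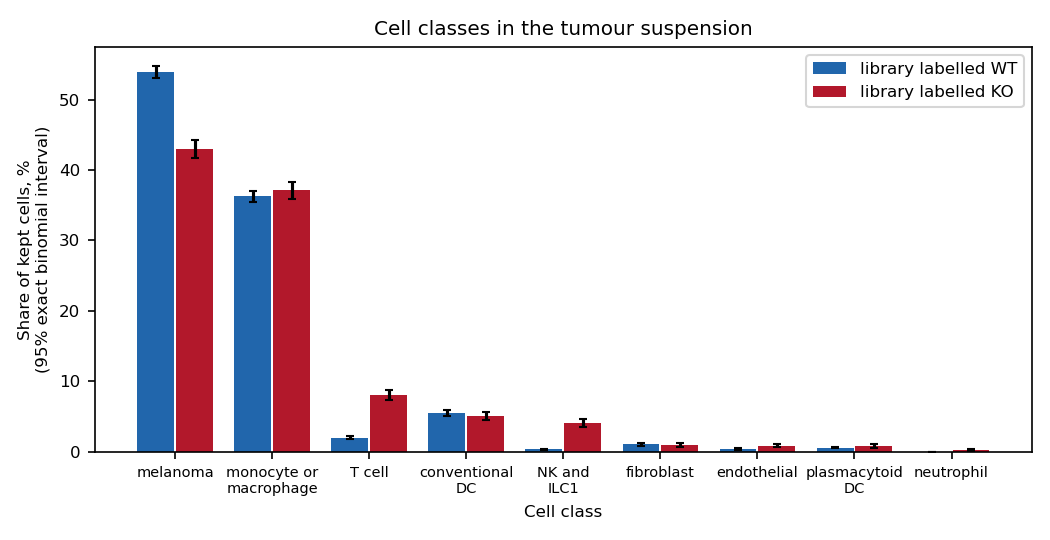
Share of kept cells in each class of the tumour libraries, in percent, with exact 95% binomial intervals. NK cells are 4.05% in the library labelled KO and 0.320% in the library labelled WT, and melanoma cells 43.0% and 53.9%.

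Melanoma cells were compared to ask what tumour cells express beside targeted NK cells, with 2519 cells labelled KO and 7927 labelled WT. Genes of antigen processing that interferon-gamma induces were higher in the library labelled KO. Psmb8, for a subunit of the immunoproteasome (ENSMUSG00000024338, chromosome 17, 34197721 to 34201454), stood at 709 CPM (702 to 717) against 44.3 CPM (42.6 to 45.9), 16.03-fold higher (15.4 to 16.7). H2-K1, for a classical MHC class I chain whose reads its paralogs can share, stood at 487 against 98.1 CPM (chromosome 17, 33996017 to 34000347), 4.97-fold higher (4.83 to 5.11). H2-T23, for the ligand of the NK receptor NKG2A, was 3.83-fold higher and Psmb9 2.94-fold. H2-DMb1 and H2-DMa, which load MHC class II, were 9.07-fold and 5.48-fold higher. Casp1, for inflammatory caspase 1, stood at 20.9 against 0.723 CPM (chromosome 9, 5298517 to 5307265), 28.9-fold higher (21.5 to 39.7). Pycard, for the adaptor that joins caspase 1 to inflammasomes, was 5.17-fold lower, at 20.2 against 104.6 CPM. Fscn1, for the actin bundler fascin, was 26.6-fold lower (22.4 to 31.8), at 2.96 against 78.7 CPM (chromosome 5, 142960343 to 142973185). Plaat3, Casp12, Il12rb1, Spp1 and Cpq were 3.80-fold to 5.26-fold higher. Mbp, Bfsp2, Rec114, Nupr1, Tmem223, Pycr1, G0s2, Rnf144a, Atf5 and Tcf7l1 were also lower, from 3.47-fold (Atf5) to 12.8-fold (Mbp).

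**Figure D4:**
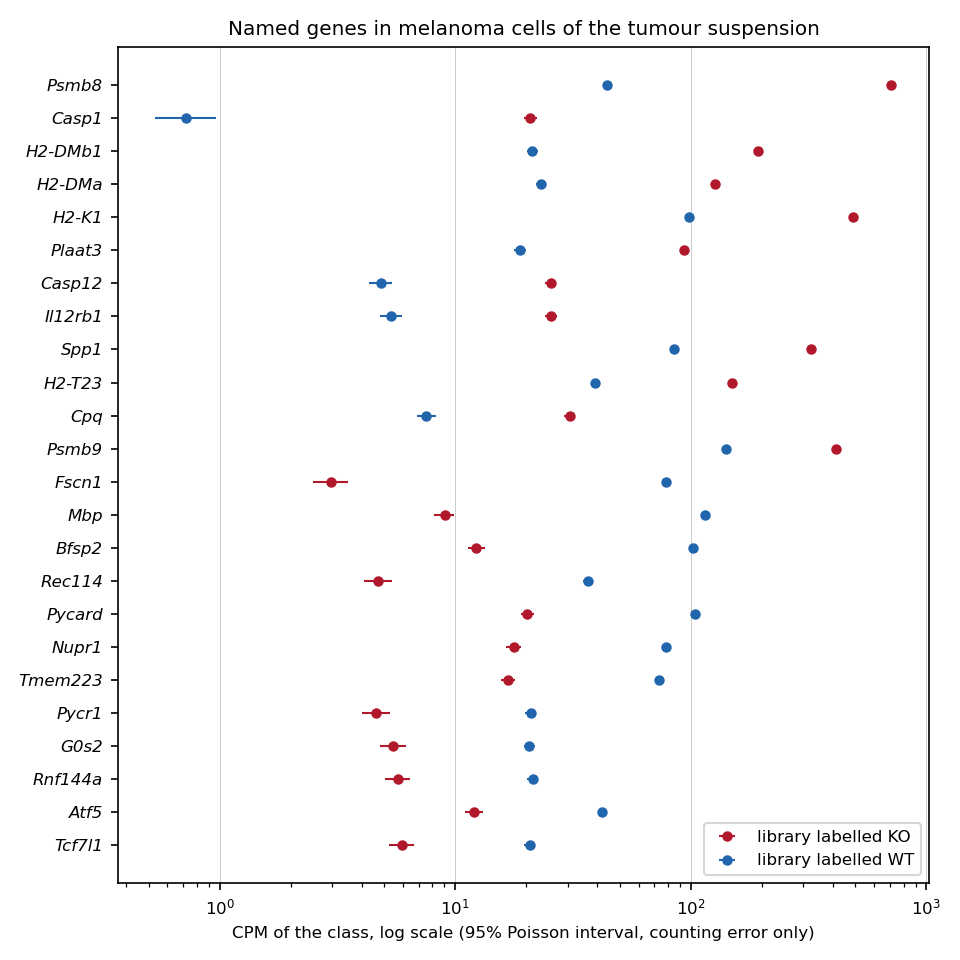
Level of named genes in melanoma cells of the tumour libraries, in CPM of the class on a log axis, with 95% Poisson intervals that cover counting error only. Psmb8 lies at 709 in the library labelled KO and 44.3 in the library labelled WT.

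By gene group, 11 of 17 interferon-gamma induced genes were at least 1.5-fold higher in melanoma cells labelled KO and none lower (median log2 ratio 0.91), among them Gbp4 (1.45) and Irgm1 (0.91). Of 18 MHC class I genes, 13 were higher and none lower (median 0.80). Of 7 MHC class II genes, 6 were higher (median 2.84), but 5 of the 7 stood at levels that RNA from myeloid cells can give. All 3 medians lay above all 10000 random lists. Type I interferon genes went the other way, 3 of 14 lower and none higher (median -0.34), with Isg15 at -1.25 and Ifit3 at -0.82. Genes of the unfolded protein and amino acid stress response were lower in 7 of 18 (median -0.53, below all random lists), with Trib3 at -1.51, Chac1 at -1.50, Phgdh at -1.33 and Asns at -1.16. Of 12 genes of apoptosis and p53, 3 were higher and 5 lower, with Cdkn1a at -1.53 and Phlda3 at -1.04. Melanocyte genes stayed within 1.5-fold in 15 of 18 and Oca2 was higher (1.15). Proliferation genes stayed within 1.5-fold in 31 of 32 (median -0.15), as did all 16 measured glycolysis genes (median 0.16), all 20 cholesterol genes (0.02) and 21 of 22 hypoxia genes (0.10). Median depth was 20328 UMIs (KO) and 7936 UMIs (WT). Clusters 9 and 5 held 33.4% and 27.1% of the class labelled KO, and clusters 4, 5 and 8 held 35.9%, 27.5% and 21.95% of that labelled WT. Within each of 6 clusters Psmb8 and Casp1 were higher and Fscn1 lower, and the interferon-gamma median ran from 0.04 in cluster 5 to 1.03 in cluster 8. The MHC class I median was 0.21 in cluster 5, 0.22 in cluster 9 and 1.26 in cluster 8, the type I interferon median ran from -1.34 in cluster 5 to 0.03 in cluster 8, and H2-K1 was lower in cluster 9 (-0.45). Cluster 9 held shallow cells, with a median of 1136 UMIs, or 0.23 relative to the median of their library.

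**Figure D5:**
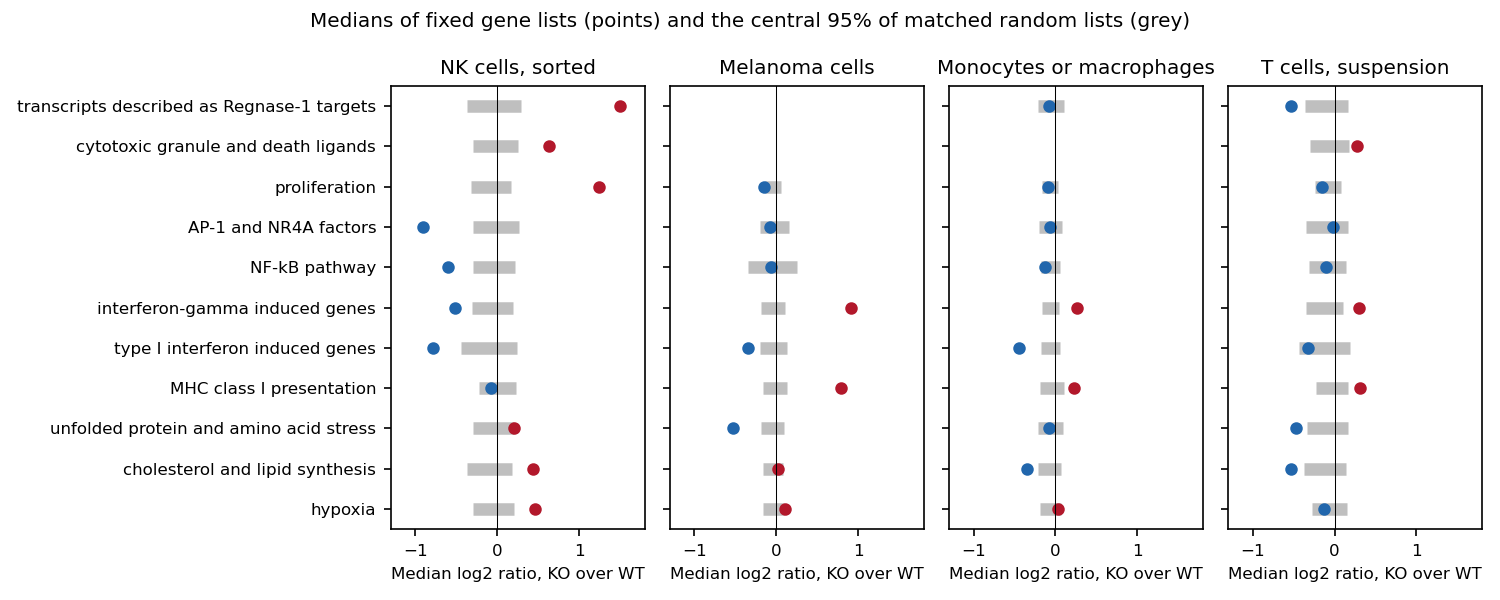
Median log2 ratio (library labelled KO over WT) of fixed gene lists with at least 5 measured members in 4 cell classes, as points, with the central 95% of 10000 matched random lists in grey. The interferon-gamma induced list lies at 0.91 in melanoma cells and -0.52 in sorted NK cells.

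Monocytes and macrophages were compared as the largest immune class of the tumour, with 2174 cells (KO) and 5334 cells (WT). Mgl2, a lectin gene of alternatively activated macrophages, was 13.6-fold lower (10.9 to 17.2) in the library labelled KO, at 7.40 against 100.6 CPM (chromosome 11, 70130329 to 70137550). It is also among the markers used here for conventional dendritic cells and the top genes of their cluster 14. Fcrls was 7.81-fold lower, Car6, which melanoma cells held at 266 (KO) against 557 CPM (WT), 5.53-fold, and the serine and asparagine synthesis genes Phgdh and Asns 4.68-fold and 5.14-fold lower. Klra17 was 10.9-fold higher (7.42 to 16.5), Cd300e 8.29-fold, Cxcl14 7.11-fold, the neutrophil chemokine gene Cxcl3 5.75-fold and the formyl peptide receptor gene Fpr1 6.58-fold. Pou2f2 was 2.09-fold higher (1.87 to 2.33) in these cells as well, at 92.4 against 44.3 CPM. Of 25 interferon-gamma induced genes, 6 were higher and 2 lower (median 0.27, above all random lists), with Gbp8 at 1.04 but Cxcl10 at -1.22. Type I interferon genes were lower in 10 of 25 (median -0.45, below all random lists), with Isg20 at -1.55. All 21 MHC class I genes stayed within 1.5-fold (median 0.23). Suppressive macrophage genes were split, with Mmp12 (1.63), Arg1 (1.28) and Spp1 (1.16) higher and Chil3 (-1.17) and Folr2 (-1.16) lower. Inflammatory genes were lower in 5 of 20, Ccl12 (-1.05) among them, while Nos2 was higher (1.04). Cholesterol synthesis genes had a median of -0.35, and of -0.09 (-0.309 to 0.024) among cells with Xist and no Y-linked counts. The 13 measured melanocyte genes had a median of -0.73 here, of -0.12 in thinned cells and of 0.00609 with means of per-cell CPM. Clusters 13, 3 and 18 held 33.4%, 26.2% and 25.9% of the class labelled KO and cluster 3 held 72.9% of that labelled WT, with median depths of 4125.5 and 1820.5 UMIs. Of cells with Xist or Y-linked counts but not both, 45.8% (KO) and 4.93% (WT) had Y-linked counts. Among those with Xist alone, Cxcl3 (32 against 20 counts) was 1.797-fold higher (0.996 to 3.31), so that no difference was detectable, Cd300e was 4.12-fold higher, and Fcrls had a ratio of 0.321 (0.218 to 0.463).

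T cells of the tumour were compared with 472 cells (KO) and 295 cells (WT). Checkpoint and inhibitory receptor genes were higher in the library labelled KO, 9 of 17 by at least 1.5-fold and none lower (median 0.59, above all random lists). Tox, a factor of exhausted T cells, stood at 1.94, Pdcd1 at 1.31 and Lag3 at 0.96. The wider list of effector and exhaustion genes had 11 higher and 10 lower of 30, with a median of -0.34 (-0.464 to 0.021), of 0.22 in thinned cells and of 0.79 with each library clustered alone. Among its lower members, Il2ra stood at -2.32, Foxp3 at -1.46 and Tnfrsf4 at -1.43. Cytokine genes were lower in 5 of 8 (median -0.92, below all random lists), with Xcl1 at -2.40 and Lta at -2.08, while Ccl5 was higher (2.01), and the median was 0.39 with each library clustered alone. Ifng was 1.87-fold lower (1.45 to 2.41) and Gzmb 1.55-fold lower (1.42 to 1.70), and Prf1 was 1.56-fold higher (1.20 to 2.04). Granule genes as a list had 7 higher and 4 lower of 14, with Gzmk at 2.51 and Gzmc at -2.73. Ccl1, with 59 counts labelled WT and 0 labelled KO, was at least 69.1-fold lower by the floor of 3 counts. Tmprss6, Osgin1 and Prr5l, with no count in the library labelled WT, were at least 8.63-fold, 6.74-fold and 6.07-fold higher by that floor. Penk was 7.16-fold lower and Car6, a gene of the melanoma cells, 6.42-fold lower, and Csf2 (1 against 26 counts) had a ratio of 0.011 (0.000267 to 0.0666). Ltf (104 against 1 count) had a ratio of 29.6 (5.20 to 1180) and Klra3 (65 against 1 count) one of 18.5 (3.21 to 742). Interferon-gamma induced genes were higher in 5 of 23 and lower in 1 (median 0.30), and MHC class I genes had a median of 0.31. The 12 measured Regnase-1 targets were lower in 5 and higher in none (median -0.53). Cluster 16, with Cd8a and Tnfrsf4 both among its top genes, held 91.5% (KO) and 99.7% (WT) of the class. Cluster 15, with Klra1 and Trgv2 among its top genes, held 8.47% (40 cells) and 0.34% (1 cell). A shift among subsets of T cells was not tested. Median depths of the class were 3216 (KO) and 1369 (WT) UMIs, and 16 melanocyte genes had a median of -0.92, and of -0.47 in thinned cells. Inflammatory macrophage genes had a median of -0.76 in this class, and of 0.17 in thinned cells. Cd3e, a marker of the class, was counted in 57.7% (KO) and 43.5% (WT) of thinned cells. Of cells with Xist or Y-linked counts but not both, 42.8% (36.3 to 49.5) labelled KO and 1.61% (0.196 to 5.71) labelled WT had Y-linked counts. Among those with Xist alone, Penk (5 against 4 counts) had a ratio of 0.521 (0.112 to 2.62) and Prf1 one of 1.37 (0.888 to 2.17), so that no difference was detectable. When each library was clustered alone, Ifng, Gzmb, Gzmc and Ccl1 were higher in the T cells labelled KO, which there took in NK cells.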

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

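The tests of the 3 patterns weighed here were all chosen after the results had been seen. Differences between cell classes were not tested, since each group is 1 library. Several log2 ratios in other classes had the opposite sign to those in sorted NK cells. In T cells of the tumour, Ifng stood at -0.90 and Gzmb at -0.63, against 1.55 and 1.49 in sorted NK cells, and both were higher (1.11 and 2.87) in T cells when each library was clustered alone. Interferon-gamma induced genes had medians of 0.91 in melanoma cells, 0.27 in monocytes or macrophages and 0.30 in T cells, against -0.52 in sorted NK cells and -0.30 in conventional dendritic cells. Proliferation genes stood at -0.15 in melanoma cells against 1.25. Cholesterol synthesis genes stood at -0.35 in monocytes or macrophages and -0.53 in T cells against 0.44. In T cells, the Regnase-1 targets had a median of -0.53 (1.496 in sorted NK cells) and the effector and exhaustion list one of -0.34 (0.29). Also in T cells, NK transcription factors stood at 0.38 (-0.58), cytokine receptors at 0.25 (-0.63) and heat shock and dissociation genes at 0.25 (-0.59). Among cells with Xist and no Y-linked counts, the intervals of the medians included 0 for cholesterol genes in monocytes or macrophages (-0.09) and, in T cells, for cytokine receptors (0.17), heat shock and dissociation genes (0.15) and the effector and exhaustion list (-0.15). Y-linked counts, left out of the named genes and used to split cells and to weigh a swap of labels, stood above the level that a count of 0 allows in every library, at 7.32 and 76.4 CPM in the sorted and 7.69 and 57.5 CPM in the tumour libraries, WT before KO.

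Transcripts described as Regnase-1 targets were higher in sorted NK cells labelled KO, with a median log2 ratio of 1.496. Another mix of male and female mice is argued against as the whole cause by a median of 1.53 among cells with Xist and no Y-linked counts. That median was 0.76, though, among cells with Y-linked counts alone. In thinned cells it was 1.35, but thinning leaves the expected make-up of each cell as it was, so this value cannot decide on depth. T cells in the class, which the sort did not remove in full (7.24% of the cells of the library labelled KO were classed as T cells), are argued against by a share of T cell RNA of 6.24%, where the excess of the 9 higher members needs a median of 83.8%. That share is the median of 11 fixed markers, a summary chosen after values of 5 of them had been seen, and it ran from 0.193% (Cd3e) to 82.6% (Trbc1), each an upper limit because NK cells can make some of these transcripts. Less decay after loss of Regnase-1 may explain the list, but 0 libraries have a partner of the same genotype from the other day, so it and the day of collection cannot be told apart.

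Zc3h12a was 3.63-fold higher in sorted NK cells labelled KO, the gene that the label says is targeted. A swap between the sorted libraries is argued against by their Y-linked level, which in the library labelled KO was 9.94 times that of the tumour library labelled WT but 1.33 times that of the tumour library labelled KO. RNA from other cells is argued against by the highest level in another class, 224.5 CPM in sorted T cells, below the 268 CPM that bounds NK cells from below. Regnase-1 is known to cut its own transcript, so a remaining transcript may decay less, and the median of the 10 other listed targets was 1.30, above all random lists. A swap of labels in both pairs was not tested, and the day of collection stays open.

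Interferon-gamma induced and MHC class I genes were higher in melanoma cells labelled KO, with medians of 0.91 and 0.80, though of 0.04 and 0.21 within cluster 5. Of 29 immune markers in these cells, mostly of macrophages or monocytes, 22 were lower (median -0.62). They do not decide on RNA from macrophages or monocytes, as those cells themselves differed in such markers. Lyz2 was counted in 77.8% (KO) and 93.3% (WT) of thinned monocytes or macrophages. H2-Aa, H2-Ab1, H2-Eb1 and Cd74, at levels that such RNA can give, would have ranked among the 12 highest genes. Nor can the markers decide on RNA from NK cells, as Klrd1 and Cd7 were lower but Prf1 and Gzma higher. Gzmc was counted in 0.666% (KO) and 0.067% (WT) of thinned melanoma cells. The median was 0.89 in thinned cells. Thinning leaves the expected make-up of each cell as it was, so this value cannot decide on depth. Extra copies of chromosome 17, which holds the MHC, are argued against as the whole cause by the 26 members on other chromosomes, with a median of 0.72 against 1.45 for the 9 on chromosome 17. Over all 293 measured genes of chromosome 17 the median was -0.128, against -0.04 for all genes, where extra copies of the chromosome would raise it. A gain of the MHC region alone was not tested. More interferon-gamma from NK cells may explain the difference, as may the later day, and no library parts these explanations. T cells are another possible source of interferon-gamma, at 8.06% (KO) against 2.01% (WT) of kept cells. Their Ifng log2 ratio was -0.90, however, and the source was not tested.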

How the results depend on the processing

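The splits by Xist and Y-linked counts and the runs without clusters of low depth were chosen after the results had been seen. No paired analysis was possible because each group is 1 library. Of the recomputed genes at 1.5-fold or more, 29 of 29 in sorted NK cells, 14 of 14 in NK cells of the suspension (9 of the 24 genes named for sorted NK cells and 5 given throughout), 24 of 24 in melanoma cells, 11 of 11 in monocytes or macrophages, 10 of 10 in conventional dendritic cells and 9 of 13 in T cells kept their direction in every alternative run. Of the list medians of that size, 13 of 14, 6 of 12, 3 of 3, 0 of 1, 4 of 5 and 3 of 5 did, in the same order, as did 3 of 3 shares of the tumour libraries and 1 of 1 of the sorted libraries. Clustering each library alone gave no ratio for NK cells of the tumour libraries or T cells of the sorted libraries. The log2 ratios given here are those that reversed, or that moved beyond counting error for the main results, and the cause was not tested.

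In sorted NK cells, Zc3h12a (1.85) was 1.93 with TMM, 1.92 with median-of-ratios, 1.795 with per-cell means, 1.79 with a pseudocount of 5, 1.96 without cells with Mki67 or Top2a counts and 1.52 in cells with Y-linked counts alone. Ifng (1.55) was 1.63, 1.62 and 1.42 with TMM, median-of-ratios and per-cell means, 1.35 in thinned cells, 1.49 with a pseudocount of 5, 1.798 in cells with Xist alone and 0.39 in cells with Y-linked counts alone. Pou2f2 (3.20) was 3.18 with at least 1000 genes, 3.19 with 5% mitochondrial counts, 3.195 at resolution 2, 3.52 with per-cell means, 3.46 in thinned cells, 2.79 with a pseudocount of 5, 3.47 without cells with Mki67 or Top2a counts, 3.177 without clusters of low depth and 2.765 in cells with Y-linked counts alone. The proliferation median reversed to -0.058 without cells with Mki67 or Top2a counts. These genes are on the list, so the filter lowers it by construction.

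In NK cells of the suspension, Ifng (3.003) was 0.82 with at least 200 genes and 8.001 in thinned cells. There the library labelled WT kept 12 cells and 0 of them had an Ifng count, so 8.001 rests on the 1 CPM added. The Regnase-1 targets reversed to -0.063 with at least 200 genes. In thinned cells, residency genes reversed to 0.034, activating receptors to 0.25 (0.02 with at least 1000 genes), interferon-gamma induced genes to 0.15, type I interferon genes to 0.029 (0.10 with no filter) and mesenchymal genes to 0.051 (0.53 with no filter). With each library clustered alone the library labelled WT had no NK cells, so that setting gives no value here. The hypoxia median there was 0.48, and 0.15 with genes of 0 counts at the floor.

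In melanoma cells, the interferon-gamma median (0.91) was 0.981 with TMM, 0.983 with median-of-ratios, 0.84 with no filter, 0.96 at 100 CPM, 0.97 without cells with Mki67 or Top2a counts and 0.78 as a mean. In monocytes or macrophages it (0.27) was 0.36 with at least 1000 genes, 0.37 with TMM and 0.35 with median-of-ratios, and the melanocyte median reversed to 0.00609 with per-cell means.

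In T cells with each library clustered alone, Ccl1 reversed to 2.39, Gzmc to 4.59, Ifng to 1.11, Gzmb to 2.87, effector cytokines to 0.39 and the effector and exhaustion list to 0.79, and T cells there took in NK cells. In thinned T cells that list reversed to 0.22 and inflammatory genes to 0.17. NK ligands in conventional dendritic cells reversed to 0.17 in thinned cells and 0.13 at 100 CPM.

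Shares are given as log2 of KO over WT. Melanoma cells (-0.33) were at -0.00122 with at least 200 genes, -0.69 with 1000, -0.064 at resolution 0.5 and -0.49 without clusters of low depth. NK cells (3.66) were at 3.09 with at least 200 genes and 5.32 with 1000. With each library clustered alone they were 0.905% (53 cells) labelled KO and 0 cells labelled WT, which gives no ratio. T cells (2.01) were at 0.46 with 200 genes, 3.20 with 1000, 1.58 with each library clustered alone, 1.70 among non-melanoma cells and 2.37 without clusters of low depth. Monocytes or macrophages (0.03) were at -0.12 with 200 genes, 0.61 with 1000, -0.35 at resolution 0.5 and -0.27 among non-melanoma cells. T cells of the sorted libraries (4.99) were at 3.84 with 200 genes. Depth limits the suspension's NK cells most, with 75534 UMIs over 47 cells labelled WT.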

Other observations

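Both tests given here were set before their results were seen. Gene levels in conventional dendritic cells, which prime T cells, were compared over 296 cells (KO) and 806 cells (WT). Ccl17, a chemokine gene that draws T cells, was 6.34-fold lower (4.70 to 8.69) in the library labelled KO, at 29.8 against 189 CPM. The growth factor gene Areg was 7.67-fold lower, St7 7.15-fold, Car6, a gene of the melanoma cells (266 against 557 CPM there), 5.09-fold and F10 (2 against 35 counts) 17.5-fold (4.50 to 150.2). The heat shock genes Hspa1b and Hspa1a, which share reads, were 6.95-fold and 5.74-fold higher, Cyp8b1 8.50-fold, Fcrla 6.17-fold and Ttc39a (36 against 3 counts) 12-fold (3.79 to 60.9). Type I interferon genes were lower in 10 of 23 and higher in none (median log2 ratio -0.50), interferon-gamma induced genes were lower in 5 of 21 and higher in 1 (median -0.30), and NF-κB pathway genes were lower in 6 of 18 (median -0.45), with Nfkbiz at -1.10 and Tnfaip3 at -1.02. The checkpoint ligand gene Cd274 stood at -0.995 and Cish at -2.14. Cluster 22, with genes of cross-presenting cells such as Clec9a and Wdfy4, held 56.4% of the class labelled KO and 21.5% of that labelled WT, and cluster 14, led by Cd209a, held 43.6% and 78.5%. Median depths were 5316 (KO) and 1899.5 (WT) UMIs, and melanocyte genes had a median of -0.79, of -0.26 in thinned cells and of -0.22 with means of per-cell CPM.

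The 686 T cells of the sorted library labelled KO were unlike the T cells of the tumour library with the same label. They had NK receptor genes, with Klrb1c at 289 CPM against 5.71 CPM and Ncr1 31.8-fold higher, and little Cd8b1 (9.13 against 786 CPM), beside a like level of Cd3e (879.6 against 979 CPM). Trdc, of gamma-delta T cells, was 9.50-fold higher, and Foxp3 had 0 against 55 counts. Zc3h12a was 4.10-fold higher (3.34 to 5.08) and Pou2f2 17.3-fold. A sort by NK receptors may have collected T cells that bear them. Whether they carry the whole NK pattern was tested on the 12 genes named as higher in sorted NK cells, and 3 of 12 were at least 1.5-fold higher (4 by the plain ratio): Irak3 (18.2-fold), Tnfrsf13b (16.7-fold) and Epas1 (2.61-fold). Pdcd1 was lower, at 99.98 against 537 CPM, as was Cxcr6, at 172 against 322.5 CPM. Both still stood above their levels in sorted NK cells labelled KO, 27.1 and 100.6 CPM. Gzmg had 0 counts in both groups of T cells and could not pass. The T cells of the tumour library were of another kind, so the count of genes does not decide whether the sorted T cells carry the pattern.

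A difference in chromosome copies between the melanoma cells of the libraries was tested on the median log2 ratio of each autosome. The largest distance from the median of all genes was 0.194 (chromosome 7, at -0.194), followed by chromosome 9 at 0.179, against 0.066 at most in monocytes or macrophages. A copy difference was to be read from 0.2 or more and argued against at 0.1 or less in every autosome. The value lay between these bounds, so a copy difference may be present in a part of the cells and stays open.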
